A study of Homo sapiens with 20 samples.

How the data were processed

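The data were 20 two-colour Agilent arrays of 5 U-2 OS lines, each stably expressing GRα, GRα-A, GRα-B, GRα-C3 or GRα-D3. Per the labels, cells received 100 nM dexamethasone (DEX) or vehicle for 6 h, and cytoplasmic RNA of both was hybridised to 1 array in Cy3 and Cy5. Each line had 2 replicates of 2 arrays, with the dyes swapped between the 2 arrays. Steps of culture, labelling and hybridisation beyond these are not given in the sources used here.

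The intensity values, which are the mean signal of a spot and the median of its local background in each channel, were made per the file headers by Agilent Feature Extraction version 7.1.1 for every replicate 1 or version 7.5.1 for every replicate 2, with no normalization. The log10 ratios in the same files were made per the file headers by that software, after background subtraction and a linear and LOWESS dye normalization. The deposited value table equals those log10 ratios with the sign turned to DEX over vehicle (largest difference 5e-06), limited to a size of 2. Its column medians ran from −0.00623 to 0.00675. Flags for spots well above background, saturated or outlying came from the same files. The arrays were read on 3 days, of which 1 covered all of replicate 2. Within replicate 1 the day went with the line. GRα-A and GRα-B were read on day 1, GRα and GRα-D3 on day 2, and GRα-C3 with 1 array on each. The term scanner batch below means the arrays read with 1 software version.

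Each array had 22153 spots, of which 1080 were controls and 21073 held 20173 distinct gene probes. Signals were background-corrected in R 4.3.3 with limma 3.58.1 (normexp, offset 50) and loess-normalized within arrays, where control and outlier-flagged spots had weight 0. Sample labels were read with jsonlite 2.0.0. Ratios were turned to log2 DEX/vehicle, spots of a probe were averaged, and the 2 arrays of a replicate were averaged, with a missing value unless both had one. Probes well above background in at least 1 channel on at least 4 of the 20 arrays were kept, which left 20062 and dropped 111. Saturated spots numbered 3 to 47 per array and outlier-flagged ones 2 to 337. Gene names were updated with a RefSeq table, by accession for 2525 probes, by symbol for 7791 and by synonym for 3026. The file's own name was used for 3172 probes, and 3659 had none. No genome build is stated, so no coordinates are given.

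One linear model with a mean per line was fitted to the 10 replicates (lmFit and eBayes; 5 residual and 3.02 prior degrees of freedom; median residual SD 0.074). It tested each line against 0, the 10 differences between lines, and any difference between the 5 lines with a moderated F-test. P-values were adjusted by Benjamini and Hochberg within each comparison, and a call had an adjusted p under 0.05. Vehicle levels were compared with an F-test on the vehicle channel after loess and Aquantile normalization. These comparisons, the alternatives, the gene lists and the rule for naming genes were chosen before the data were examined.

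The 27 lists held 766 genes, of which 741 were measured, each by its brightest probe. They were canonical glucocorticoid-induced genes, cytokines and chemokines, NF-κB pathway genes, immediate early genes, pro-apoptotic and anti-apoptotic genes, DNA replication genes, mitosis genes, cell cycle inhibitors, osteoblast genes, matrix genes, TGF-β targets, cholesterol, fatty acid and glucose metabolism, ion channels and transporters, interferon-stimulated genes, metallothioneins, clock genes, heat shock genes, receptor chaperones, ribosomal proteins, and markers of haematopoietic, epithelial, endothelial and hepatocyte types. None of the nuclear-retained RNAs was measured, so the purity of the fraction was not examined. Lists were tested with camera over 11916 genes, with a preset correlation of 0.01 and again with an estimated one, over 130 tests within lines and 260 between lines. For some lists the estimate lay below the preset value (−0.001 for cytokines and chemokines, −0.003 for matrix genes). Correlation between genes therefore does not account for the higher p-values of these lists under that setting. For cytokines and chemokines in GRα the unadjusted camera p rose from 0.000172 to 0.00784 although the correlation used was lower. The 2 settings thus differ in more than the correlation. A call lost with the estimated one does not show that the call depended on correlation between genes.

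Named genes had a gene symbol and met 1 of these rules. In each line they were the 10 largest rises and 10 largest falls among calls with 1 sign on all 4 arrays. In each list and line they were up to 4 called members with the largest change. Between lines they were the 15 with the largest range past the F-test and the 3 largest differences in each direction per comparison. At the vehicle level they were the 10 with the largest range past the F-test. NR3C1, FKBP5, TSC22D3, DUSP1, PER1, SGK1, KLF9, ZBTB16, MT2A, IL6, CXCL8 and CCL2 were always named. Some genes that met a rule are not reported here.

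Deviations of replicates with the same number correlated with r = −0.141 to 0.29 over the 10 pairs of lines, so the number was not taken to pair them. That was examined for the DEX/vehicle ratios and not for the vehicle channel. The alternatives were other background, normalization, filter, weight and threshold settings, the deposited log10 ratios, intensity trend and robust eBayes, the replicate number (which is also the scanner batch) as a block, the extraction day as a block, models of the 20 arrays, the omission of the array with conflicting labels, a fit of the compared lines alone, and the omission of each replicate in turn. Array models with a dye term per batch, with and without that array or with it counted as GRα-D3, were added after seeing the data. The method was tested on simulated data. In them the dye effect cancelled exactly between the 2 arrays of a replicate, without other array noise, and probes varied independently. The shares below hold for that setting only. Planted changes of log2 0.5, 1 and 2 were called at 86.6%, 96.8% and 100% of probes for a line against 0 and at 76.1%, 91.9% and 100% for a difference of 2 lines. For the F-test the shares were 67.2%, 88.7% and 100%, and false calls were 12 of 201, 12 of 191 and 13 of 184 calls in these 3 tests. Data with no planted change gave 0 calls in limma for a line against 0. The difference of 2 lines and the F-test were not counted on those data.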

Results

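The responses to a glucocorticoid were compared between 5 lines of U-2 OS, a human osteosarcoma cell line. Each stably expressed the human glucocorticoid receptor α (GRα), labelled GRα, GRα-A, GRα-B, GRα-C3 or GRα-D3. Whether the line labelled GRα, without a letter, made 1 form or several was not examined. The lettered forms are made from alternative translation starts of a single transcript, and from A to D3 they have progressively shorter N-terminal regions. Cells received 100 nM dexamethasone (DEX), a synthetic ligand of the receptor, or vehicle for 6 h, and cytoplasmic RNA was taken. The question, as the series title puts it in other words, was which target genes distinguish the N-terminal forms. On each 2-colour array the DEX and vehicle RNA of 1 line were hybridised together. Each line had 2 replicates and each replicate had 2 arrays with the dyes swapped, which gave 20 arrays and 10 replicates. All means below are log2 DEX/vehicle with n = 2 replicates per line, and the SE of each mean comes from the spread shared by all lines. The labels number the replicates as biological without naming separate cultures, so p-values measure only the spread between these samples, which may be technical. Where 5 values are listed they follow the order GRα, GRα-A, GRα-B, GRα-C3, GRα-D3.

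Median spot intensities were 184 to 553 in Cy3 and 150 to 585 in Cy5, and 90.7% to 99.3% of gene spots were well above background in a channel. The local background was 56 to 71 on the arrays of every replicate 1 and 269 to 293 on those of every replicate 2, which were read with different software versions. Each such batch therefore held 1 replicate of every line, and the value of a single replicate is also a value within a batch. Replicates of a line correlated across all probes with r = 0.768, 0.871, 0.684, 0.831 and 0.841, where probes are not independent replicates. The number of arrays limits the precision of every value. The 2 dye-swapped arrays correlated with r = 0.342 to 0.706, except for GRα replicate 2 (r = −0.281) and GRα-D3 replicate 2 (r = 0.125). The channel labels of 1 array of GRα-C3 replicate 1 name GRα-D3, while its title names GRα-C3. It was kept as GRα-C3.

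DEX raised a common set of genes in all 5 lines. FLRT3, a transmembrane protein of cell adhesion and growth factor signalling, rose 21.0-fold, 26.3-fold, 15.8-fold, 15.7-fold and 29.2-fold (log2 4.39, 4.72, 3.98, 3.97 and 4.87, SE 0.28; limma adjusted p = 0.000443, 0.000113, 0.000346, 0.000126 and 0.000103). RGS2, which dampens G protein signalling, rose by log2 3.25, 4.02, 3.26, 3.70 and 3.0, with a value from only 1 replicate in GRα-B. CLPTM1L, a membrane protein linked to cell survival, rose by 2.38, 3.38, 2.78, 3.27 and 3.12 (SE 0.15). SLC19A2, a thiamine transporter, rose by 2.24, 2.11, 2.30, 2.40 and 2.82, and NFKBIA, the inhibitor of NF-κB, rose by 1.38, 2.12, 2.06, 2.52 and 2.30 (SE 0.13). The calls of these 5 genes held in every line whichever replicate was left out, except that RGS2 has no value in GRα-B without its replicate 1. FLRT3 had adjusted p = 0.0674 in GRα without background correction, and its call in GRα-B was also lost under that setting.

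The genes that fell in all 5 lines included regulators of growth and of early transcription. FHL2, a LIM-domain adaptor of transcription and the cytoskeleton, had log2 values of −2.01, −3.23, −2.52, −3.39 and −3.41 (SE 0.26), which was 10.6-fold lower in GRα-D3. PMEPA1, a TGF-β-induced membrane protein, fell with log2 values of −1.92 in GRα, −1.87 in GRα-B, −1.97 in GRα-C3 and −2.56 in GRα-D3 (SE 0.13). The early response genes IER2 and IER3 fell too, with −1.79, −2.26, −2.33, −2.85 and −1.65 for IER2 and −1.88, −1.61, −1.69, −1.71 and −2.13 for IER3. BCL3, a co-regulator of NF-κB, had −1.64, −2.37, −2.42, −2.35 and −2.39 (SE 0.175). Leaving out 1 replicate ended a call among these only for FHL2 in GRα, with adjusted p = 0.0617 without GRα replicate 1 and 0.0817 without GRα replicate 2. Without background correction BCL3 was not called in any line.

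**Figure D1:**
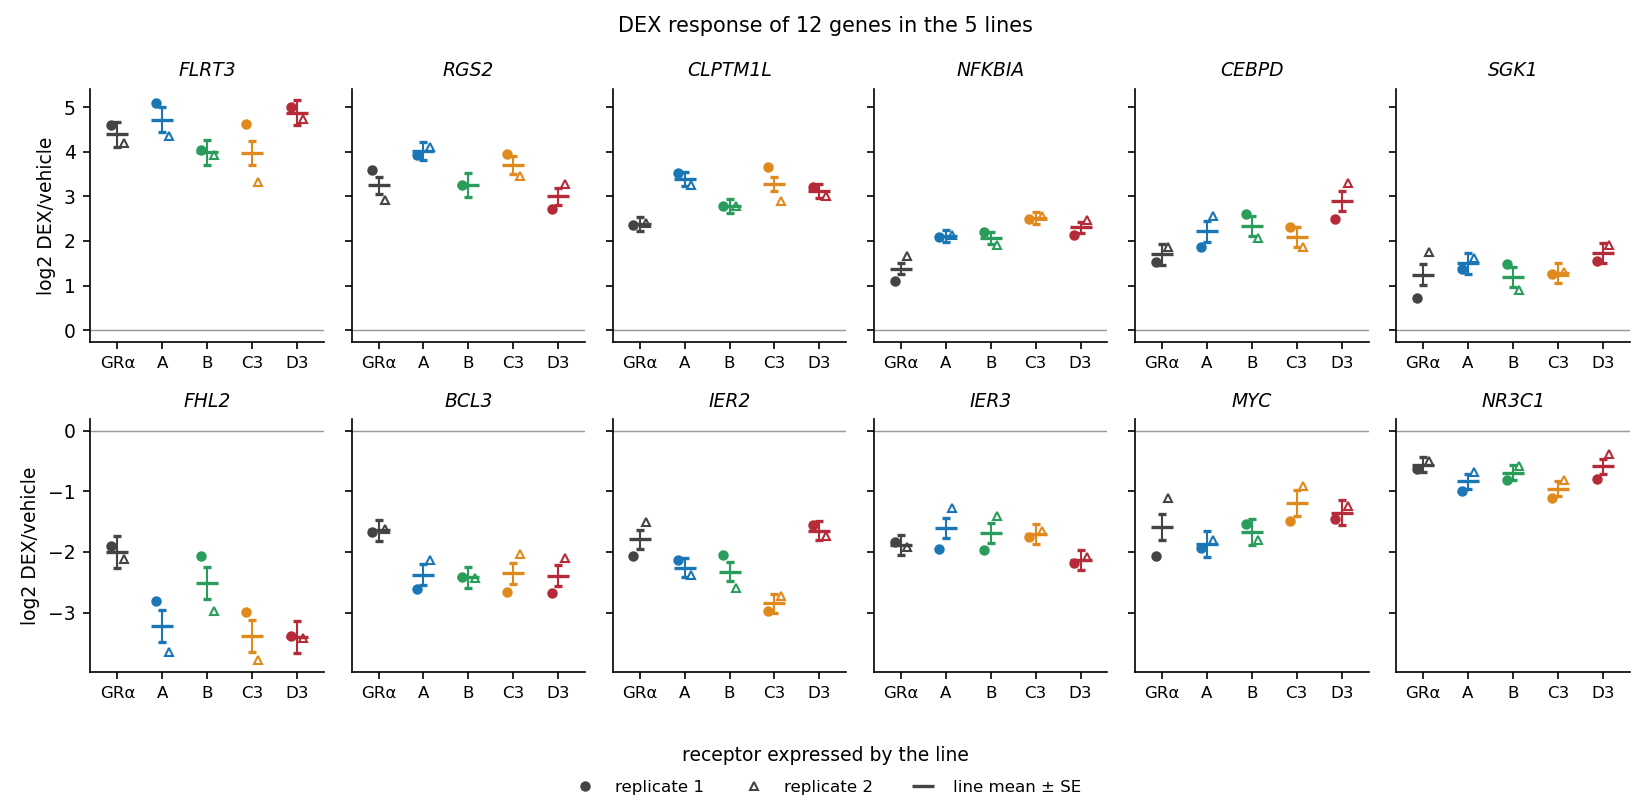
Log2 DEX/vehicle (vertical axis) of 12 genes in the 5 lines (horizontal axis). Circles are replicate 1, triangles replicate 2, and bars the line mean with its SE. FLRT3 lies between 3.97 and 4.87 and FHL2 between −3.41 and −2.01 in the 5 line means.

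Of 12 genes named whatever their values, few passed the test in every line. No probe sequences were available, so whether the NR3C1 probe reads the introduced receptor RNA, the cells' own or both is not known. The signal of this receptor gene fell, with log2 −0.56, −0.84, −0.69, −0.96 and −0.59 (SE 0.12, adjusted p = 0.0328, 0.0032, 0.00937, 0.00149 and 0.0214). Its call was lost in GRα without replicate 1 (adjusted p = 0.289) or 2 (adjusted p = 0.184), in GRα-A without its replicate 1 (adjusted p = 0.0699), in GRα-B without its replicate 1 (adjusted p = 0.0658) and in GRα-D3 without its replicate 1 (adjusted p = 0.223). The clock gene PER1 rose by 0.59, 0.78, 0.90, 0.93 and 0.66, and was stable to each left-out replicate in GRα-B and GRα-C3 only. It was lost in GRα without GRα replicate 2 (adjusted p = 0.374) or either GRα-A replicate (adjusted p = 0.0628), in GRα-A without its replicate 1 (adjusted p = 0.0714) or 2 (adjusted p = 0.0742) and in GRα-D3 without its replicate 1 (adjusted p = 0.0628) or 2 (adjusted p = 0.231). SGK1, a kinase that regulates sodium transport, rose by 1.25, 1.5, 1.19, 1.29 and 1.74. SGK1 was lost without replicate 2 of GRα (adjusted p = 0.18), replicate 1 (adjusted p = 0.0503) or 2 (adjusted p = 0.0827) of GRα-A, replicate 1 of GRα-B (adjusted p = 0.0983), replicate 1 (adjusted p = 0.0617) or 2 (adjusted p = 0.0875) of GRα-C3 and replicate 2 of GRα-D3 (adjusted p = 0.0745), each for its own line.

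The other genes of that set passed in some lines only, and some in none. FKBP5, a receptor co-chaperone, had 0.39, 0.49, 0.70, 0.42 and 0.72 and passed in GRα-B (adjusted p = 0.0397) and GRα-D3 (adjusted p = 0.0409). In GRα-B the FKBP5 call survived only the omission of GRα-B replicate 2, and in GRα-D3 only the omission of either GRα-B replicate (elsewhere adjusted p = 0.0503 to 0.354). TSC22D3, an anti-inflammatory mediator, passed in GRα-A (0.47, adjusted p = 0.0271; 0.228 without its replicate 1 and 0.162 without its replicate 2) and GRα-C3 (0.41, adjusted p = 0.0434; 0.168 without its replicate 1, 0.306 without its replicate 2 and 0.0737 without either GRα-A replicate). DUSP1, a phosphatase of MAP kinases, passed in GRα-D3 (1.27, adjusted p = 0.0311; 0.181 without its replicate 1, 0.254 without its replicate 2 and 0.0665 without either GRα-A replicate). ZBTB16, a transcription factor, passed in GRα-C3 (0.84, adjusted p = 0.0197; 0.0643 without its replicate 1 and 0.255 without its replicate 2). The chemokine CXCL8 had −1.23, −1.07, −1.40, −0.58 and −0.72 and passed in the first 3 lines, but was lost without either replicate of GRα (adjusted p = 0.173 and 0.368), GRα-C3 or GRα-D3 (adjusted p = 0.0615) in GRα, without GRα-A replicate 1 (adjusted p = 0.368) or either GRα-D3 replicate (adjusted p = 0.0504) in GRα-A, and without GRα-B replicate 2 (adjusted p = 0.178) in GRα-B. KLF9 (0.29 to 0.69), IL6 (−0.27 to −0.06) and CCL2 (−1.55 to −0.58) passed in no line, and MT2A passed in none either, with 1.02 in GRα-D3 (adjusted p = 0.057).

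In GRα, 646 probes rose and 627 fell, and 69 and 42 of them changed at least 2-fold. DLL1, a ligand of Notch receptors, rose 3.56-fold (log2 1.83, SE 0.075, adjusted p = 8.2e-05). The nuclear receptor NR0B1 rose by 1.86 and the transcription factor SNAI1, which drives loss of epithelial adhesion, by 2.09. Among the falls, MYC had −1.59 and ENC1, an actin-associated protein, −1.70, both called with each replicate left out in turn. NR0B1 was lost without GRα replicate 1 (adjusted p = 0.0501) or 2 (adjusted p = 0.118), and SNAI1 without GRα replicate 1 (adjusted p = 0.101). The 1273 calls of GRα fell to 244 without its replicate 1 and 267 without its replicate 2.

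In GRα-A, 1443 probes rose and 1817 fell, and 169 and 84 of them changed at least 2-fold. NR0B1 rose 7.0-fold, SNAI1 7.22-fold, the stress-responsive NDRG1 6.07-fold, the transcription factor FOXC1 5.87-fold and the vitamin D receptor gene VDR 5.61-fold. The Notch effector HES1 fell 7.67-fold (log2 −2.94, SE 0.35), and the matricellular CCN1 fell 7.45-fold. The protease ADAMTS6 (−2.06), the LIM protein AJUBA (−1.95) and the inducible chaperone HSPA1A (−1.87) fell as well. These genes kept their calls in GRα-A without each replicate in turn. The 3260 calls of GRα-A fell to 954 without its replicate 1 and 880 without its replicate 2.

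In GRα-B, 857 probes rose and 1549 fell, and 125 and 74 of them changed at least 2-fold. The replicates of this line correlated least (r = 0.684), and with GRα-B alone in the fit only 99 probes were called. The SE shared by all lines may therefore be too small for GRα-B. SMIM3, a small membrane protein, rose 8.65-fold and SNAI1 6.60-fold. NSDHL, an enzyme of cholesterol synthesis, rose 5.08-fold, NLRP3, the inflammasome sensor, 5.07-fold, CEBPD, a transcription factor of the acute phase response, 5.05-fold and PCSK5, a proprotein convertase, 4.88-fold. The receptor-anchoring protein gene ERBIN fell 3.32-fold (log2 −1.73, SE 0.062, adjusted p = 2.75e-05) and CCN1 5.59-fold. These calls held without each replicate in turn. The 2406 calls of GRα-B fell to 840 without its replicate 2.

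In GRα-C3, 1544 probes rose and 1734 fell, and 190 and 93 of them changed at least 2-fold. SMIM3 rose 8.96-fold, VDR 7.23-fold, ATP4A, a subunit of the gastric proton pump, 6.93-fold, and SNTG2, a syntrophin, 6.10-fold. The estrogen-forming enzyme gene HSD17B1 rose 5.90-fold. IER2 fell 7.20-fold, the immediate early factor EGR1 5.49-fold and BBC3, which promotes apoptosis, 3.85-fold. These calls held without each replicate in turn. The 3278 calls of GRα-C3 fell to 1885 without its replicate 1 and 1309 without its replicate 2.

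In GRα-D3, 764 probes rose and 1157 fell, and 114 and 89 of them changed at least 2-fold. CEBPD rose 7.45-fold, the membrane estrogen receptor gene GPER1 6.96-fold (log2 2.80, SE 0.32, adjusted p = 0.002), NSDHL 5.38-fold and the carbonic anhydrase gene CA2 5.19-fold. LIMS3, a focal adhesion protein gene, fell 6.53-fold, the membrane protein gene EMP1 4.30-fold, the matrix protein gene TGFBI 4.48-fold and the enamel-related TUFT1 4.07-fold. These calls held without each replicate in turn. The 1921 calls of GRα-D3 fell to 937 without its replicate 1 and 411 without its replicate 2. With the scanner batch as a block the 5 lines had 1521, 3535, 2727, 3535 and 2288 calls.

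**Figure D2:**
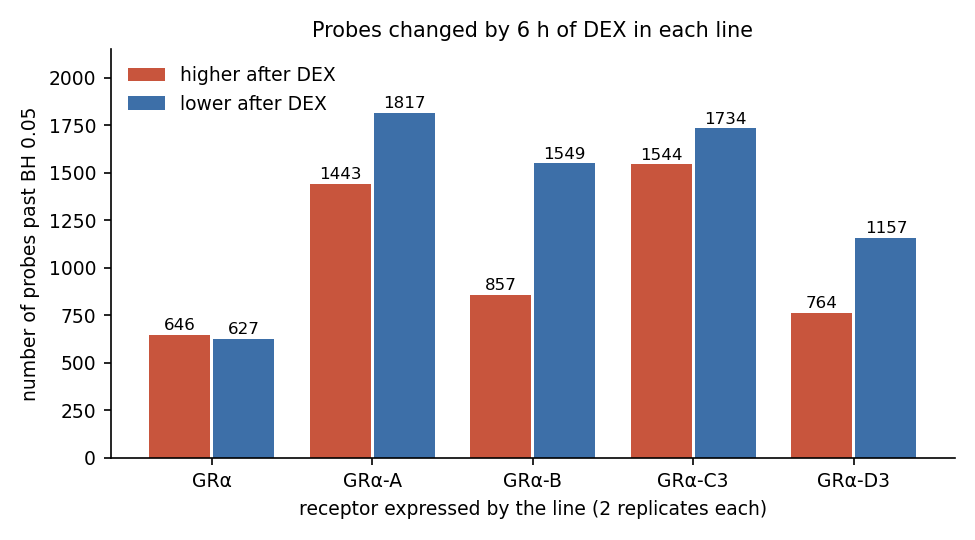
Number of probes (vertical axis) past a Benjamini-Hochberg adjusted p of 0.05 in each line (horizontal axis), with rises and falls in separate bars. GRα had 646 rises and 627 falls, and GRα-C3 had 1544 and 1734.

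Part of the known glucocorticoid targets rose in each line. Counts of list members here and below moved with the processing, and without background correction no list had more members called in either direction in any line than given. Of 36 measured canonical glucocorticoid-induced genes, 7, 8, 9, 10 and 9 rose and 0, 1, 1, 1 and 2 fell (7, 9, 11, 12 and 11 higher and 1, 1, 1, 1 and 3 lower adjusted over the list alone), among them RGS2, NFKBIA and CEBPD. Median centring gave 14 rises in GRα-A, and without background correction 2, 5, 4, 7 and 6 rose. The set test camera gave adjusted p = 0.00357, 0.00479, 0.00063, 0.00259 and 0.000989, but adjusted p = 0.582, 0.59, 0.571, 0.574 and 0.574 with an estimated correlation. Of 31 inflammatory cytokines and chemokines none rose, and 6, 7, 4, 5 and 4 fell (8, 7, 6, 5 and 6 adjusted over the list alone), such as IL18 with −0.91 in GRα-A and −1.17 in GRα-D3. Without background correction 1, 2, 1, 2 and 2 of them fell, with median centring 2 rose in GRα-A, and with the deposited log10 ratios 1 rose in GRα-D3. Camera placed this list lower in GRα, GRα-A, GRα-B and GRα-D3 (adjusted p = 0.0016, 0.0366, 0.0153 and 0.0153), but adjusted p = 0.18, 0.262, 0.215 and 0.215 with an estimated correlation, and with median centring the list's median turned positive in GRα-A (0.051) and GRα-D3 (0.003). In GRα-C3 it had adjusted p = 0.0524, and 0.0281 with the scanner batch as a block, but adjusted p = 0.297 with an estimated correlation. Of 22 NF-κB pathway and feedback genes 1, 3, 3, 2 and 2 rose and 3, 3, 4, 3 and 3 fell (1, 4, 3, 3 and 3 higher and 3, 4, 4, 6 and 3 lower adjusted over the list alone), with NFKBIA higher and BCL3 lower in every line and no set call (lowest adjusted p = 0.29).

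Members of the immediate early and heat shock lists fell in every line, and camera called both lists lower in 4 lines with the preset correlation only. Of 28 immediate early and AP-1 genes 10, 10, 10, 11 and 5 fell and 0, 1, 1, 1 and 2 rose (11, 11, 11, 13 and 6 lower and 1, 2, 1, 2 and 2 higher adjusted over the list alone). Scaling between arrays left 5, 5, 8, 8 and 3 falls, and no background correction left 5, 6, 6, 6 and 3. FOSL1, an AP-1 subunit, had −1.29 in GRα-A and −1.20 in GRα-B. A dimmer FOSL1 probe had −0.19 and −0.27 in these lines and was called only in GRα-B. Camera placed the list lower in GRα, GRα-A, GRα-B and GRα-C3 (adjusted p = 4.28e-06, 0.00301, 0.000426 and 3.29e-05), but adjusted p = 0.18, 0.25, 0.208 and 0.18 with an estimated correlation, and in GRα-D3 it had adjusted p = 0.0721. Of 23 heat shock and unfolded protein response genes 6, 10, 7, 10 and 6 fell and 0, 0, 0, 0 and 1 rose (9, 12, 11, 14 and 8 lower and 0, 0, 1, 0 and 4 higher adjusted over the list alone), with the co-chaperone DNAJB1 at −0.87 in GRα, −0.74 in GRα-B and −0.92 in GRα-C3. The same 4 lines passed camera (adjusted p = 2.38e-05, 4.82e-05, 0.00479 and 5.26e-06; adjusted p = 0.18, 0.18, 0.215 and 0.18 with an estimated correlation), and GRα-D3 did not (adjusted p = 0.533). Of 26 receptor chaperones and coregulators 7, 9, 8, 9 and 8 fell and 1, 3, 3, 3 and 3 rose (8, 12, 9, 13 and 9 lower and 3, 4, 3, 3 and 3 higher adjusted over the list alone), with no set call (lowest adjusted p = 0.0763, in GRα-C3, where it was 0.035 with the scanner batch as a block; adjusted p = 0.363 with an estimated correlation). The histone deacetylase HDAC2 had −0.58 in GRα-A.

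Some mitosis genes fell in GRα-A, GRα-B and GRα-C3. Of 36 measured, 0, 14, 8, 14 and 0 fell and 0, 0, 1, 0 and 6 rose (0, 19, 12, 22 and 0 lower and 0, 0, 2, 0 and 6 higher adjusted over the list alone). Camera gave adjusted p = 5.3e-06, 0.00357 and 1.07e-07 in those 3 lines (adjusted p = 0.463, 0.574 and 0.386 with an estimated correlation), against 0.684 in GRα and 0.283 in GRα-D3. In GRα-C3 the cyclin CCNA2 had −0.46 and the kinetochore protein CENPF −0.50, and in GRα-A the spindle protein ASPM had −0.56. In GRα-D3 ASPM had 0.26, a call lost without its replicate 1 (adjusted p = 0.0567) or 2 (adjusted p = 0.14), and the list's median of 0.019 turned to −0.063 with median centring, where none of its members was higher. With that centring 0, 23, 4, 4 and 0 mitosis genes fell. The median was 0.10 in replicate 1 and −0.06 in replicate 2 of GRα-D3. Of 37 DNA replication genes 2, 3, 2, 3 and 3 rose and 1, 6, 5, 6 and 1 fell (4, 4, 3, 4 and 3 higher and 2, 7, 5, 6 and 1 lower adjusted over the list alone; lowest adjusted p = 0.297). With median centring 0, 0, 0, 1 and 0 of them rose and 1, 12, 4, 0 and 1 fell. Of 18 cell cycle inhibitors 1, 2, 1, 1 and 2 rose and 0, 4, 2, 4 and 0 fell (2, 3, 1, 2 and 2 higher and 3, 5, 2, 4 and 1 lower adjusted over the list alone; lowest adjusted p = 0.259). CDKN2C, an inhibitor of cyclin D kinases, had −0.55 in GRα-A and −0.85 in GRα-C3, and CDKN2D −0.69 and −0.93.

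Apoptosis genes went both ways. Of 35 pro-apoptotic genes 3, 4, 4, 4 and 1 rose and 4, 6, 4, 4 and 6 fell (4, 4, 4, 4 and 2 higher and 5, 6, 4, 7 and 7 lower adjusted over the list alone; lowest adjusted p = 0.268), and the caspase CASP6 had 1.24 in GRα-A and 1.22 in GRα-C3. Of 16 anti-apoptotic genes 0, 0, 1, 0 and 0 rose and 2, 4, 2, 3 and 2 fell (0, 0, 1, 0 and 0 higher and 2, 4, 3, 4 and 2 lower adjusted over the list alone, lowest adjusted p = 0.089). The survival kinase PIM1 had −1.08 in GRα-A and −1.13 in GRα-C3, but a dimmer PIM1 probe had −0.08 and −0.06 there and was called in no line.

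Matrix and TGF-β genes moved in both directions in every line, and these lists passed camera in GRα-D3 alone. Of 57 matrix remodelling and adhesion genes 2, 6, 7, 6 and 15 fell and 4, 7, 6, 8 and 5 rose (3, 10, 7, 7 and 20 lower and 6, 8, 7, 8 and 8 higher adjusted over the list alone), and GRα-D3 passed camera (adjusted p = 0.0101; adjusted p = 0.208 with an estimated correlation). With median centring 10 matrix genes fell in GRα-A and 10 in GRα-D3. The protease gene PLAU had −1.02, −1.25, −1.10 and −1.55 in the 4 lettered lines and the collagen gene COL6A1 rose by 1.37, 1.55 and 1.04 in GRα, GRα-A and GRα-C3. Of 26 TGF-β and SMAD targets 7, 10, 8, 11 and 8 fell and 2, 3, 3, 3 and 2 rose (10, 11, 10, 11 and 11 lower and 2, 4, 3, 6 and 3 higher adjusted over the list alone). Without background correction 1, 4, 4, 5 and 3 of them fell and 0, 2, 0, 2 and 0 rose, and with scaling between arrays 2, 6, 7, 8 and 5 fell. GRα-D3 passed camera (adjusted p = 0.00571; adjusted p = 0.208 with an estimated correlation), with −0.16 and −0.27 as medians of its replicates, and GRα did so only with the scanner batch as a block (adjusted p = 0.0769 without it and 0.0393 with it; adjusted p = 0.363 with an estimated correlation). No difference between GRα-D3 and another line passed for TGF-β targets (lowest adjusted p = 0.0602). The ligand gene TGFB2 had −1.17 and the differentiation inhibitor ID3 −1.47 in GRα-D3. Of 29 osteoblast and bone matrix genes 1, 2, 1, 1 and 2 rose and 2, 3, 4, 3 and 5 fell, with the same counts adjusted over the list alone (lowest adjusted p = 0.202). Median centring gave 7 rises and 4 falls of them in GRα-A, and turned the list's median there from −0.035 to 0.046. The collagen gene COL1A1 fell in all lines (−0.55, −0.97, −0.90, −0.65 and −0.71) and the parathyroid hormone receptor gene PTH1R had 1.11 in GRα-D3.

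Metabolic groups moved in mixed directions, and none passed camera except cholesterol genes in GRα-C3 with the scanner batch as a block (adjusted p = 0.0421, against 0.0769 without it; adjusted p = 0.767 with an estimated correlation). Of 23 cholesterol genes 3, 3, 3, 3 and 4 rose and 0, 6, 4, 9 and 1 fell (3, 3, 3, 3 and 5 higher and 2, 9, 9, 13 and 2 lower adjusted over the list alone; lowest adjusted p = 0.0769). Without background correction 0, 0, 0, 3 and 0 of them fell, and with median centring 0, 12, 7, 6 and 2. The isomerase gene IDI1 had 1.01 in GRα-A and 1.28 in GRα-D3, and the squalene epoxidase gene SQLE had −1.32 in GRα-C3. Of 35 fatty acid and triglyceride genes 2, 5, 2, 4 and 1 rose and 3, 9, 8, 10 and 3 fell (4, 6, 2, 6 and 2 higher and 7, 10, 10, 11 and 6 lower adjusted over the list alone; lowest adjusted p = 0.322), with the lipogenic factor SREBF1 at −1.31 in GRα-A and −1.44 in GRα-C3. Of 39 glucose metabolism genes 0, 0, 1, 1 and 0 rose and 1, 3, 2, 1 and 2 fell (0, 0, 1, 0 and 0 higher and 1, 2, 2, 1 and 2 lower adjusted over the list alone; lowest adjusted p = 0.52), and the insulin receptor substrate gene IRS1 had −0.80 in GRα-B. Without background correction none of them fell in any line, and with median centring 6 rose and 8 fell in GRα-A. Of 29 ion channels and transporters 3, 4, 4, 3 and 4 rose and 2, 5, 3, 4 and 3 fell (3, 4, 4, 7 and 4 higher and 2, 6, 3, 5 and 5 lower adjusted over the list alone; lowest adjusted p = 0.542). Median centring gave 7 rises and 4 falls of them in GRα-A. The sodium pump subunit gene ATP1B1 had −1.09 in GRα-D3. Of 18 clock genes 1, 4, 5, 3 and 4 rose and 3, 5, 4, 4 and 4 fell (3, 6, 5, 4 and 4 higher and 4, 6, 5, 4 and 6 lower adjusted over the list alone; lowest adjusted p = 0.552). Of 33 interferon-stimulated genes 1, 2, 1, 1 and 1 rose and 0, 1, 0, 3 and 1 fell (1, 1, 0, 1 and 1 higher and 0, 1, 0, 2 and 1 lower adjusted over the list alone; lowest adjusted p = 0.394).

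Of 10 metallothionein genes, 1 rose and 1 fell in GRα-D3 and 1 fell in GRα-B (6 higher and 1 lower in GRα-D3 and 1 lower in GRα-B adjusted over the list alone). Their median was 1.15 in GRα-D3, with 1.40 and 0.88 in its replicates, and camera gave adjusted p = 0.0433 there, but adjusted p = 0.582 with an estimated correlation and 0.0604 with the scanner batch as a block. Of 60 ribosomal protein genes, a reference list, 3, 16, 6, 8 and 0 rose and none fell (3, 17, 6, 8 and 0 higher adjusted over the list alone). With median centring 0, 0, 0, 5 and 0 of them rose. Camera placed them higher in GRα, GRα-A, GRα-B and GRα-C3 (adjusted p = 7.16e-10, 5.26e-06, 0.000135 and 0.00555; adjusted p = 0.398, 0.511, 0.574 and 0.667 with an estimated correlation) and gave 0.502 in GRα-D3, and with median centring the median turned negative in GRα-A (−0.037) and GRα-D3 (−0.026). Markers of other cell types passed no set test. Of 24 haematopoietic markers CD79A (0.26, GRα-A) and CD3D (0.57, GRα-C3) rose, with 1 in GRα-C3 adjusted over the list alone, and CD79A was −0.026 with median centring and lost without either replicate of GRα-A, GRα-C3 or GRα-D3. Of 18 epithelial markers 0, 1, 0, 1 and 2 rose and 0, 1, 2, 1 and 1 fell (0, 0, 0, 1 and 2 higher and 0, 0, 2, 1 and 3 lower adjusted over the list alone), with the keratin KRT5 at 1.40 in GRα-D3. Of 13 endothelial markers only VWF rose, in GRα-A (0.36) and GRα-C3 (0.96), also adjusted over the list alone, and of 19 hepatocyte markers 0, 2, 0, 3 and 1 rose (2, 3 and 0 in GRα-A, GRα-C3 and GRα-D3 adjusted over the list alone). Median centring called 4 endothelial markers higher in GRα-A. The lowest adjusted camera p of these 4 marker lists were 0.259, 0.673, 0.297 and 0.387. The VWF call in GRα-A was lost without its replicate 1 (adjusted p = 0.196) or 2 (adjusted p = 0.113).

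**Figure D3:**
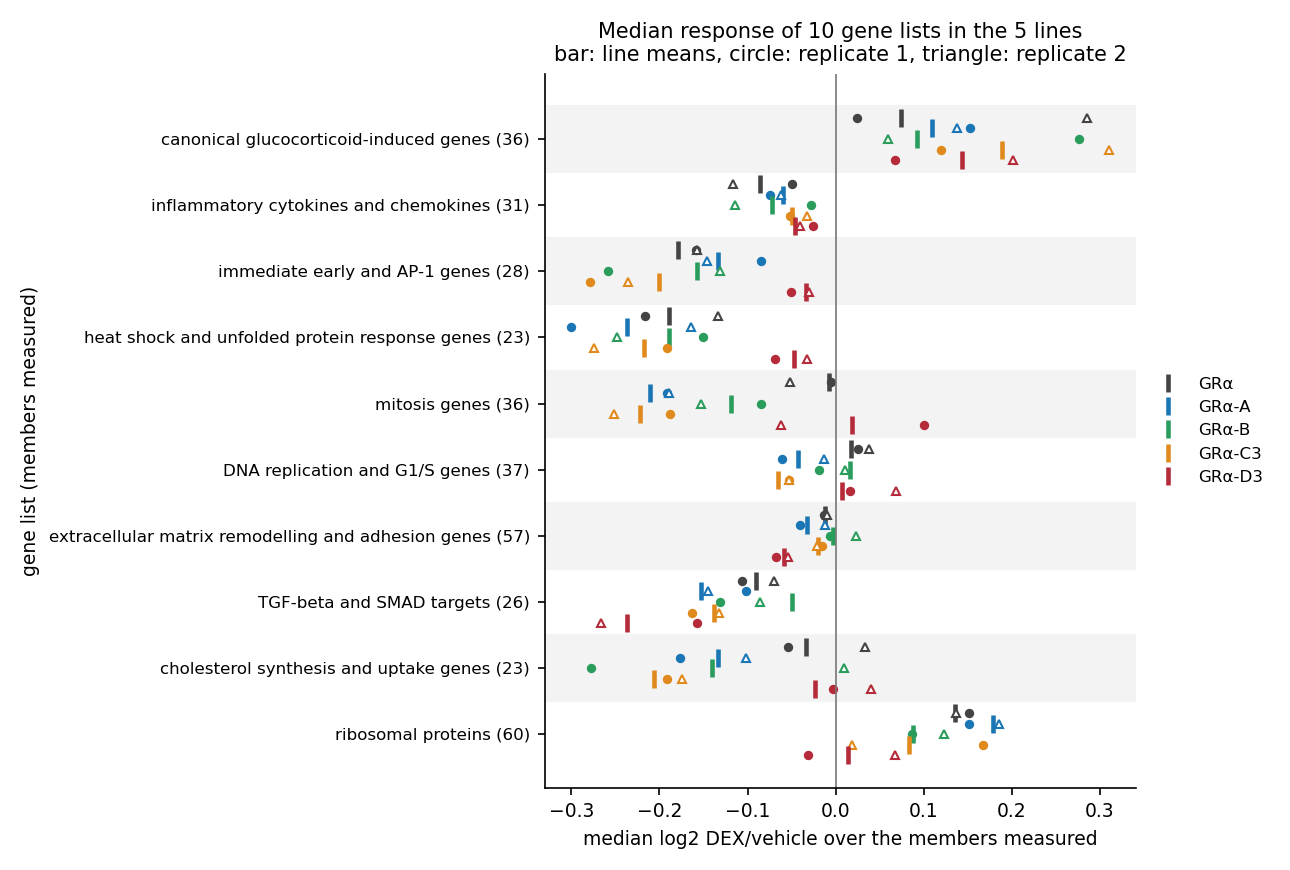
Median log2 DEX/vehicle (horizontal axis) of 10 gene lists (vertical axis, members measured in parentheses) in the 5 lines. Bars are medians of the line means, circles replicate 1 and triangles replicate 2. Heat shock genes lie at −0.24 in GRα-A and −0.05 in GRα-D3 (−0.485 and −0.17 with median centring), and the ribosomal median of GRα-A (0.18) turned to −0.037 and that of GRα-D3 (0.014) to −0.026 with median centring.

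Most calls were shared between lines. Of the 20062 probes, 594 were called in all 5 lines and 593 of these moved in 1 direction, 209 up and 384 down. GRα-A and GRα-C3 shared 1007 rises, where independent lists would share 110.9, and 1312 falls against 156.7 (r = 0.91 across probes, which are not independent replicates). GRα-C3 and GRα-D3 shared 433 rises against 58.7 and 710 falls against 99.6, with 24 probes called in opposite directions (r = 0.731). The lines shared no control samples, but the tests of a probe shared 1 estimate of its spread. Calls can therefore overlap beyond the numbers for independent lists. Calls seen in 1 line alone numbered 66, 582, 372, 642 and 453, but only 0, 0, 1, 0 and 3 of them passed the test of a difference between lines.

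The response to DEX differed between the lines for 83 probes of 61 named genes (F-test over the 5 lines). FOXC1 rose in the first 4 lines by 1.03, 2.55, 1.55 and 2.02 and had −0.45 in GRα-D3 (SE 0.14, F-test adjusted p = 0.0183). In the batch of replicate 1 FOXC1 had 1.20, 2.34, 1.42, 1.87 and −0.64, and in that of replicate 2 it had 0.87, 2.77, 1.68, 2.16 and −0.26. A dimmer FOXC1 probe had 0.17, 0.29, 0.22, 0.18 and −0.12. DLL1 rose in GRα (1.83), GRα-A (1.6), GRα-C3 (1.12) and GRα-D3 (0.64) and had 0.15 in GRα-B (adjusted p = 0.014). FOXC1 was lost without GRα-A replicate 2 (adjusted p = 0.0578) or GRα-C3 replicate 2 (adjusted p = 0.0534), and DLL1 without GRα-A replicate 2 (adjusted p = 0.0578).

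Further genes responded least in GRα-D3. HSD17B1 had 1.76, 1.89, 1.86, 2.56 and 0.35 (adjusted p = 0.0302), the lysosomal protease CTSH 1.19, 1.19, 1.21, 1.81 and 0.10 (adjusted p = 0.0472) and THAP4 1.34, 1.75, 1.43, 1.82 and 0.41 (adjusted p = 0.0235). The TNF receptor family gene TNFRSF12A fell least there, with −0.77, −1.05, −1.07, −1.71 and −0.39 (adjusted p = 0.0398). The NF-κB inhibitor gene NFKBIE had the opposite sign in GRα-D3, with 0.40, 1.14, 0.63, 1.18 and −0.59 (adjusted p = 0.0473). Others responded most in GRα-D3, namely CA2 (1.73, 1.16, 0.58, 0.99 and 2.38; adjusted p = 0.0331) and the interferon regulatory factor gene IRF8 (0.96, 1.23, 1.23, 1.56 and 2.23; adjusted p = 0.0367). KDF1 (0.41, 1.76, 1.22, 2.46 and 0.65; adjusted p = 0.0472), NLRP3 (0.65, 1.73, 2.34, 2.47 and 1.29; adjusted p = 0.0472), CA4 (0.27, 1.01, 0.81, 1.78 and 0.28; adjusted p = 0.0214), the mTOR partner gene RPTOR (0.53, 1.11, 0.49, 1.49 and 0.21; adjusted p = 0.0351) and SCGB2A1 (0.37, 0.53, 1.13, 1.58 and 0.34; adjusted p = 0.0288) responded most in GRα-C3. The calls of these 12 genes did not hold with 1 replicate left out, which leaves a lone value in a line and less power. Without GRα-C3 replicate 2 the adjusted p of all 12 lay between 0.0534 (HSD17B1, KDF1 and CA4) and 0.142 (CTSH).

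GRα-D3 had the lowest or the highest of the line means in 63 of the 83 probes, and GRα in 17. Each probe counts for 2 lines here, so these counts overlap. Such extremes were not counted for GRα-A, GRα-B and GRα-C3, so GRα-D3 was not shown to be extreme most often. The sign was the same in all lines for 56 probes. The count was 42, 5, 211, 7 and 17 without replicate 1 of GRα, GRα-A, GRα-B, GRα-C3 and GRα-D3. Without replicate 2 of GRα, GRα-A, GRα-C3 and GRα-D3 it was 30, 0, 3 and 14. With the scanner batch as a block it was 146, of which 76 were among the 83.

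**Figure D4:**
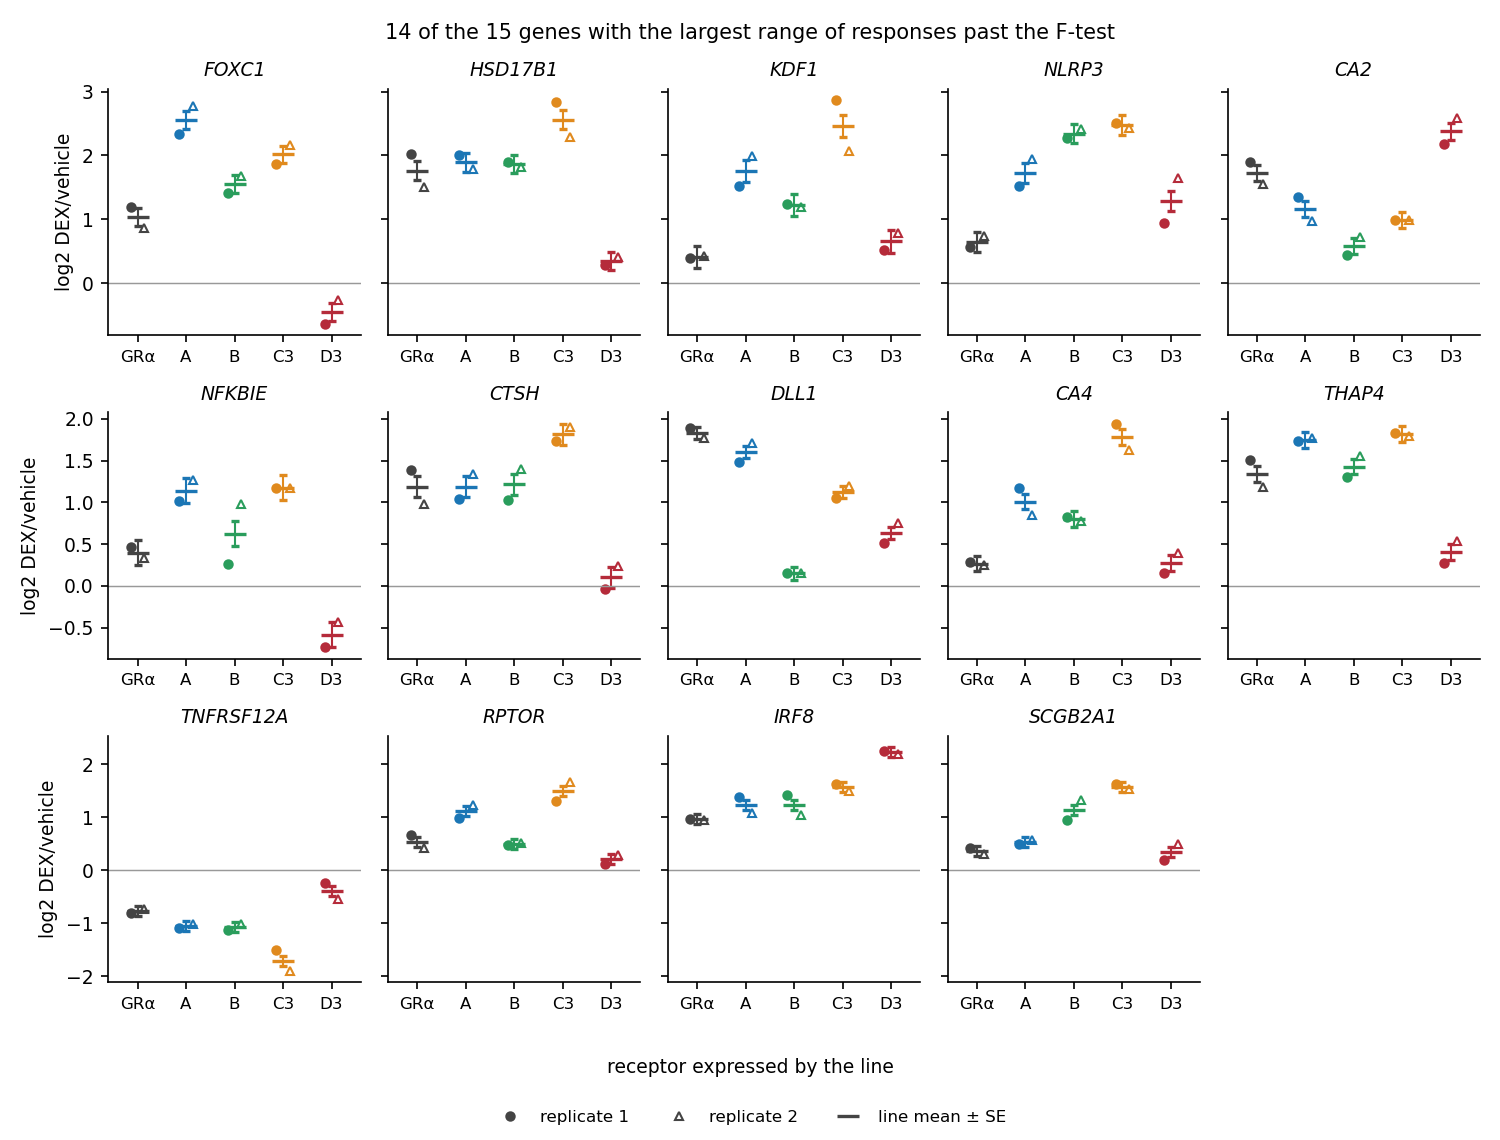
Log2 DEX/vehicle (vertical axis) of 14 of the 15 genes with the largest range of line means past the F-test, in the 5 lines (horizontal axis). Circles are replicate 1, triangles replicate 2, and bars the line mean with its SE. FOXC1 lies at −0.64 and −0.26 in GRα-D3 and between 0.87 and 2.77 in the other lines.

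Set against GRα, the lettered lines differed at few genes. In GRα-C3, KDF1, a regulator of keratinocyte growth, responded higher by 2.05 (SE 0.25, adjusted p = 0.031), NLRP3 by 1.82 (adjusted p = 0.0324) and CA4, a membrane carbonic anhydrase, by 1.52 (adjusted p = 0.0129). In GRα-D3, IRF8 was higher by 1.27 (adjusted p = 0.0247), while the difference was −1.20 for DLL1 (adjusted p = 0.0154), −1.07 for the cytoskeletal PHLDB2 (adjusted p = 0.0213) and −0.99 for PLAU (adjusted p = 0.0213). In GRα-B the difference from GRα was −1.68 for DLL1 (adjusted p = 0.00497) and −0.54 for the homeobox gene GSC (adjusted p = 0.0223). The counts were 0 probes for GRα-A in limma (1195 at an unadjusted p under 0.05), 2 for GRα-B, 25 for GRα-C3 (21 higher, 4 lower) and 17 for GRα-D3 (9 higher, 8 lower; 3 higher and 0 lower with scaling between arrays). With the scanner batch as a block they were 6, 56 and 38 for GRα-B, GRα-C3 and GRα-D3.

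These calls did not hold with 1 replicate left out. That leaves a lone value in a line and less power, so a lost call does not show that 1 replicate made the difference. KDF1, for example, had 0.397 and 0.423 in the replicates of GRα and 2.865 and 2.062 in those of GRα-C3. Without GRα replicate 2 the adjusted p was 0.2 for KDF1, 0.187 for NLRP3, 0.0965 for CA4, 0.0847 for IRF8, 0.07 for PLAU, 0.0752 for PHLDB2 and 0.0653 for DLL1 in GRα-D3. Without GRα-B replicate 2 it was 0.0772 for DLL1 and 0.213 for GSC in GRα-B. For GRα-A the count was 5 without GRα replicate 1, 2 without GRα replicate 2 and 4 without GRα-A replicate 2. For GRα-B it was 7 and 4 without replicates 1 and 2 of GRα, 66 and 0 without those of GRα-B and 1 without any other. For GRα-C3 it was 15 and 2 without replicates 1 and 2 of GRα, 11 without either of GRα-A, 48 without either of GRα-B, and 12 and 9 without those of GRα-C3. For GRα-D3 it was 10 and 7 without those of GRα, 11 without either of GRα-A, 7 without either of GRα-C3, and 8 and 6 without those of GRα-D3.

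Among GRα-A, GRα-B and GRα-C3, GSC set GRα-B apart from both others, and DLL1 set it apart from GRα-A only. GSC responded lower in GRα-B than in GRα-A by −0.68 (adjusted p = 0.00767) and higher in GRα-C3 than in GRα-B by 0.62 (adjusted p = 0.0152), and DLL1 was lower in GRα-B than in GRα-A by −1.45 (adjusted p = 0.00788). COL6A1 also differed between GRα-B and GRα-A (−1.19, adjusted p = 0.0376). The comparisons gave 3 probes for GRα-B against GRα-A (6 with the scanner batch as a block), 1 for GRα-C3 against GRα-B (3 with the block; 8 higher and 1 lower with scaling between arrays) and 0 for GRα-C3 against GRα-A in limma (841 at an unadjusted p under 0.05). Without GRα-B replicate 2, DLL1 and GSC had adjusted p = 0.0787 against GRα-A and GSC had 0.102 against GRα-C3, and COL6A1 was lost without any 1 of the 10 replicates (adjusted p = 0.059 to 0.129). GSC against GRα-A was also lost without GRα-A replicate 1 (adjusted p = 0.0504). GRα-B against GRα-A had 5 and 0 probes without replicates 1 and 2 of GRα-B and 7 without GRα-A replicate 2. GRα-C3 against GRα-B had 33 without GRα-B replicate 1 and 0 without any other replicate except GRα-C3 replicate 1, and GRα-C3 against GRα-A had 1 without either GRα-B replicate.

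GRα-D3 differed from each of the 3 other lettered lines. FOXC1 was lower in GRα-D3 by −3.0 against GRα-A (SE 0.20, adjusted p = 0.00407), −2.46 against GRα-C3 (adjusted p = 0.00616) and −2.0 against GRα-B (adjusted p = 0.0172). HSD17B1 was lower by −2.21 against GRα-C3 (adjusted p = 0.00623) and −1.52 against GRα-B (adjusted p = 0.0452), and ATP4A by −2.65 against GRα-C3 (adjusted p = 0.0345). CA2 was higher by 1.21 against GRα-A (adjusted p = 0.0398), 1.79 against GRα-B (adjusted p = 0.0182) and 1.39 against GRα-C3 (adjusted p = 0.0145). EGR1, which fell in GRα-C3, was higher in GRα-D3 by 2.35 (adjusted p = 0.022), RRAD, a small GTPase, by 0.96 against GRα-A (adjusted p = 0.00858), and TRAF4, a TNF receptor adaptor, by 1.00 against GRα-B (adjusted p = 0.0182). The counts were 100 probes against GRα-A (42 higher, 58 lower), 38 against GRα-B (22 higher, 16 lower) and 307 against GRα-C3 (144 higher, 163 lower). With median centring they were 1 higher and 4 lower against GRα-A and 13 higher and 76 lower against GRα-C3, and with scaling between arrays 7 higher and 6 lower against GRα-A. With the scanner batch as a block the count against GRα-A was 159.

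The FOXC1 calls against GRα-A and GRα-C3 and the HSD17B1 call against GRα-C3 held without each replicate in turn. FOXC1 against GRα-B was lost without GRα-D3 replicate 1 (adjusted p = 0.0598) or GRα-B replicate 2 (adjusted p = 0.0703), and TRAF4 without the same replicates (adjusted p = 0.0598 and 0.0608). RRAD was lost without GRα-A replicate 1 (adjusted p = 0.0641) or 2 (adjusted p = 0.0518). EGR1 (adjusted p = 0.0937), CA2 against each line (adjusted p = 0.16, 0.0682 and 0.07), ATP4A (adjusted p = 0.121) and HSD17B1 against GRα-B (adjusted p = 0.134) were lost without GRα-D3 replicate 2 and others. Against GRα-A the count was 66 without either replicate of GRα, 15 without either of GRα-A, 188 without either of GRα-B, 64 without either of GRα-C3, and 20 and 15 without those of GRα-D3. Against GRα-B it was 12 without either of GRα-A, 187 and 0 without those of GRα-B, and 18 and 17 without those of GRα-D3. Against GRα-C3 it was 187 without either of GRα-A, 79 and 132 without those of GRα-C3, and 81 and 90 without those of GRα-D3.

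Some gene groups differed between lines in camera with the preset correlation, and none did under the setting that estimates it. For matrix genes that estimate was −0.003, so correlation between genes does not account for their loss. The 2 settings differ in more than the correlation, so how far it accounts for the loss of the other lists cannot be told. Mitosis genes had lower responses than in GRα in GRα-A (adjusted p = 3.31e-11; adjusted p = 0.438 with an estimated correlation) and GRα-C3 (1.55e-13; adjusted p = 0.38 with an estimated correlation), and higher responses in GRα-D3 than in GRα-A (6.04e-13; adjusted p = 0.393 with an estimated correlation) and GRα-C3 (1.08e-13; adjusted p = 0.38 with an estimated correlation). Against GRα-C3, 2 mitosis genes were higher in GRα-D3, and 12 adjusted over the list alone. Heat shock genes fell less in GRα-D3 than in GRα-C3 (adjusted p = 1.12e-08; adjusted p = 0.166 with an estimated correlation), with 3 higher and 7 adjusted over the list alone, but with median centring, where the difference was not tested, the list's medians were −0.17 in GRα-D3 and −0.16 in GRα-C3, against −0.485 in GRα-A and −0.309 in GRα-B. Immediate early genes fell less too (adjusted p = 0.00166; adjusted p = 0.38 with an estimated correlation), with 3 higher and 8 adjusted over the list alone. Matrix genes responded lower in GRα-D3 than in GRα (adjusted p = 8.24e-05; adjusted p = 0.166 with an estimated correlation), with 2 lower and 10 adjusted over the list alone. Ribosomal protein genes, the reference list, missed the threshold between GRα-D3 and GRα-C3 (adjusted p = 0.0577) and had lower responses in GRα-D3 than in GRα (adjusted p = 2.35e-08; adjusted p = 0.648 with an estimated correlation), GRα-A (adjusted p = 1.21e-06; adjusted p = 0.768 with an estimated correlation) and GRα-B (adjusted p = 0.000943; adjusted p = 0.829 with an estimated correlation), but with median centring the medians were −0.026 in GRα-D3, 0.205 in GRα, −0.037 in GRα-A and 0.008 in GRα-B, so the direction against GRα-A turned. In all, 39 of 260 such tests passed, 39 with the scanner batch as a block and 0 with an estimated correlation, against 27 of 130 tests within lines, of which the block gave 30 and the estimated correlation 0.

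Before treatment few probes were called different between the lines. DHRS2, a short-chain dehydrogenase gene, was the named gene whose vehicle level was called different without the scanner batch as a block. Its log2 intensities were 13.79, 10, 9.70, 10.99 and 12.06 (SE 0.20, adjusted p = 0.0402), a 17.1-fold range. A second DHRS2 probe had 13.50, 9.85, 9.67, 10.84 and 11.91 (adjusted p = 0.0159). Another probe, which has no gene name here and was chosen after its values were seen, had 11.29, 10.17, 9.87, 6.20 and 6.36 (adjusted p = 8.24e-05). NR3C1 had vehicle levels of 8.46, 8.63, 8.43, 8.57 and 8.86 (SE 0.27, adjusted p = 1), a range of 0.43 that was not called. This fit had no term for the scanner batch, so the SE includes the gap between batches. Replicate 1 had NR3C1 levels of 8.46, 8.82, 8.84, 9.03 and 9.16 and replicate 2 had 8.45, 8.45, 8.03, 8.11 and 8.55. GRα-D3 was highest in both, so equal levels of the RNA that this probe reads were not shown. Whether that is the introduced receptor RNA is not known. In all, 3 probes passed the F-test in limma, against 600 at an unadjusted p under 0.05 and 63 with the scanner batch as a block. Between 2 lines at most 9 probes were called, all lower in GRα-C3 than in GRα. The F-test count was 1 without either replicate of GRα, GRα-A, GRα-B or GRα-C3.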

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

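The tests of the smaller response and of the array with conflicting labels for GRα-D3, both tests for GRα and the test of the array's identity were chosen after the results were seen. The batch test for GRα-D3 was written before.

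A test of the difference itself set the lines apart in 9 comparisons. It found 2 probes for GRα-B against GRα, 25 for GRα-C3 against GRα, 17 for GRα-D3 against GRα, 3 for GRα-B against GRα-A, 100 for GRα-D3 against GRα-A, 1 for GRα-C3 against GRα-B, 38 for GRα-D3 against GRα-B, 307 for GRα-D3 against GRα-C3 and 83 for the 5 lines together. The same F-test set apart the genes with the largest ranges of line means, of which 14 are given: FOXC1 (3), HSD17B1 (2.213), KDF1 (2.053), NLRP3 (1.819), CA2 (1.792), NFKBIE (1.761), CTSH (1.71), DLL1 (1.68), CA4 (1.516), THAP4 (1.405), TNFRSF12A (1.314), RPTOR (1.283), IRF8 (1.266) and SCGB2A1 (1.234).

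The response of GRα-D3 differed from those of the other lines. If the scanner batch were the whole cause, the deviation of GRα-D3 from the mean of the other 4 lines would not recur in the other batch, but it did with r = 0.614, against at most 0.113 with another line. A smaller overall response does not account for all of it, since 22.8% of the 307 probes that set it apart from GRα-C3 were called in GRα-D3 and either larger there (25) or of opposite sign (45), while 252 lay nearer to 0 in GRα-D3. Without the array with conflicting labels the lowest of 3 counts was 69% of its value (100 to 69, 307 to 313 and 83 to 79). This test cannot decide whether that array plays a part. It enters neither mean of GRα-D3 against GRα-A, and GRα-D3 RNA on it would shrink the difference from GRα-C3. A difference between the receptor forms may remain as a hypothesis, but the design has 1 line per form, and a difference between clones was not tested.

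Fewer probes were called in GRα (1273) than in the other lines (1921 to 3278). Several values go against a dye effect in GRα replicate 2 as the whole cause. An effect equal on both arrays of a replicate cancels in its mean, and the slope of GRα on the other lines was 0.728 in replicate 1 and 0.72 in replicate 2. With its own replicate 2 left out, GRα had 267 calls and the other lines had 411 to 1309, and with a dye term per batch GRα had 2168 and the others 2916 to 4142. These values did not settle it, because the count of GRα itself ran from 903 to 1823 when replicate 2 of another line was left out, and because an effect unequal between the 2 arrays was not measured. A smaller overall response could not be settled either. Both GRα slopes lay below the lowest other slope (0.735, GRα-D3 replicate 1), but by a margin of 0.007, while the slopes of a line's replicates differed by a median of 0.133. The amount of receptor protein was not measured.

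The channel labels of 1 array of GRα-C3 replicate 1 name GRα-D3. If the array held GRα-D3, its deviations would correlate more with GRα-D3 than with GRα-C3 of the other batch. The correlation was higher with GRα-C3 by 0.357 (0.271 against −0.086), which argues against that. No biological explanation was tested for this pattern.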

How the results depend on the processing

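The tests added after the data were seen were the array models with a dye term per batch and the replicate block of the gene lists, and tests of all other settings were planned. The main counts in limma and camera were GRα 1273, GRα-A 3260, GRα-B 2406, GRα-C3 3278, GRα-D3 1921, GRα-A against GRα 0, GRα-B against GRα 2, GRα-C3 against GRα 25, GRα-D3 against GRα 17, GRα-B against GRα-A 3, GRα-C3 against GRα-A 0, GRα-D3 against GRα-A 100, GRα-C3 against GRα-B 1, GRα-D3 against GRα-B 38, GRα-D3 against GRα-C3 307, the F-test 83, the vehicle F-test 3, gene lists 27, gene lists between lines 39. Values that moved by over 1.5 times are given below, and the cause was not tested unless stated.

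With the setting no background correction, the values were GRα 406, GRα-A 1827, GRα-B 994, GRα-C3 1956, GRα-D3 1181, GRα-B against GRα 0, GRα-C3 against GRα 2, GRα-D3 against GRα 3, GRα-B against GRα-A 0, GRα-C3 against GRα-A 2, GRα-D3 against GRα-A 13, GRα-C3 against GRα-B 2, GRα-D3 against GRα-B 11, GRα-D3 against GRα-C3 55, the F-test 16. With the setting median centring, the values were GRα 471, GRα-A 5288, GRα-B 1310, GRα-C3 1687, GRα-D3 1030, GRα-B against GRα 1, GRα-C3 against GRα 12, GRα-D3 against GRα 5, GRα-B against GRα-A 1, GRα-D3 against GRα-A 5, GRα-C3 against GRα-B 0, GRα-D3 against GRα-B 11, GRα-D3 against GRα-C3 89, the F-test 17. With the setting scale between arrays, the values were GRα 636, GRα-B against GRα 0, GRα-C3 against GRα 65, GRα-D3 against GRα 3, GRα-B against GRα-A 0, GRα-D3 against GRα-A 13, GRα-C3 against GRα-B 9, GRα-D3 against GRα-B 5, the F-test 35. With the setting 20 arrays, random replicate effect, the values were GRα 2415, GRα-D3 3179, GRα-A against GRα 137, GRα-B against GRα 61, GRα-C3 against GRα 410, GRα-D3 against GRα 403, GRα-B against GRα-A 63, GRα-C3 against GRα-A 52, GRα-D3 against GRα-A 789, GRα-C3 against GRα-B 251, GRα-D3 against GRα-B 489, GRα-D3 against GRα-C3 1217, the F-test 1172. With the setting 20 arrays with a dye term, the values were GRα 2287, GRα-D3 3009, GRα-A against GRα 98, GRα-B against GRα 43, GRα-C3 against GRα 375, GRα-D3 against GRα 338, GRα-B against GRα-A 58, GRα-C3 against GRα-A 52, GRα-D3 against GRα-A 676, GRα-C3 against GRα-B 208, GRα-D3 against GRα-B 421, GRα-D3 against GRα-C3 1169, the F-test 1016. With the setting extraction day as a block, the values were GRα 2568, GRα-D3 3307, GRα-A against GRα 388, GRα-B against GRα 168, GRα-C3 against GRα 682, GRα-D3 against GRα 847, GRα-B against GRα-A 174, GRα-C3 against GRα-A 145, GRα-D3 against GRα-A 1272, GRα-C3 against GRα-B 437, GRα-D3 against GRα-B 873, GRα-D3 against GRα-C3 1700, the F-test 1950. With the setting 20 arrays with a dye term per batch, the values were GRα 2168, GRα-D3 2916, GRα-A against GRα 89, GRα-B against GRα 40, GRα-C3 against GRα 334, GRα-D3 against GRα 302, GRα-B against GRα-A 43, GRα-C3 against GRα-A 39, GRα-D3 against GRα-A 624, GRα-C3 against GRα-B 159, GRα-D3 against GRα-B 379, GRα-D3 against GRα-C3 1050, the F-test 882. With the setting 20 arrays with a dye term per batch, less the array with conflicting labels, the values were GRα 2312, GRα-D3 3081, GRα-A against GRα 104, GRα-B against GRα 41, GRα-C3 against GRα 294, GRα-D3 against GRα 345, GRα-B against GRα-A 49, GRα-C3 against GRα-A 25, GRα-D3 against GRα-A 693, GRα-C3 against GRα-B 168, GRα-D3 against GRα-B 411, GRα-D3 against GRα-C3 818, the F-test 875. With the setting 20 arrays with a dye term per batch, that array counted as GRα-D3, the values were GRα 2113, GRα-D3 3586, GRα-A against GRα 38, GRα-B against GRα 20, GRα-C3 against GRα 129, GRα-D3 against GRα 101, GRα-B against GRα-A 29, GRα-C3 against GRα-A 2, GRα-C3 against GRα-B 77, GRα-D3 against GRα-C3 203, the F-test 289. With the setting BH 0.05 and at least 1.5-fold, the values were GRα 318, GRα-A 666, GRα-B 559, GRα-C3 789, GRα-D3 533, GRα-B against GRα 1, GRα-D3 against GRα-A 65, GRα-D3 against GRα-C3 170. With the setting BH 0.01, the values were GRα 339, GRα-A 1424, GRα-B 890, GRα-C3 1621, GRα-D3 640, GRα-B against GRα 1, GRα-C3 against GRα 0, GRα-D3 against GRα 0, GRα-D3 against GRα-A 6, GRα-C3 against GRα-B 0, GRα-D3 against GRα-B 0, GRα-D3 against GRα-C3 44, the F-test 1, the vehicle F-test 1. With the setting only the lines of the comparison in the fit, the values were GRα-B 99, GRα-B against GRα 0, GRα-C3 against GRα 2, GRα-D3 against GRα 0, GRα-B against GRα-A 0, GRα-C3 against GRα-A 4, GRα-C3 against GRα-B 0, GRα-D3 against GRα-B 0, GRα-D3 against GRα-C3 171. With the setting Agilent LogRatio column, the values were GRα-B against GRα 0, GRα-D3 against GRα 2, GRα-B against GRα-A 1, GRα-D3 against GRα-A 49, GRα-C3 against GRα-B 0, GRα-D3 against GRα-B 14, the F-test 27. With the setting replicate block, the values were GRα-B against GRα 6, GRα-C3 against GRα 56, GRα-D3 against GRα 38, GRα-B against GRα-A 6, GRα-D3 against GRα-A 159, GRα-C3 against GRα-B 3, the F-test 146, the vehicle F-test 63. With the setting without the array with conflicting labels, the values were GRα-B against GRα 1, GRα-C3 against GRα-B 8. With the setting series matrix, the values were GRα-B against GRα 0, GRα-D3 against GRα 2, GRα-B against GRα-A 1, GRα-D3 against GRα-A 49, GRα-C3 against GRα-B 0, GRα-D3 against GRα-B 14, the F-test 27. With the setting eBayes with an intensity trend, the values were GRα-C3 against GRα 40, GRα-C3 against GRα-B 7. With the setting outlier spots kept, the values were GRα-D3 against GRα 9, GRα-D3 against GRα-B 24. With the setting estimated correlation, the values were gene lists 0, gene lists between lines 0.

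Over the omission of each replicate in turn, which leaves a lone sample assumed to vary like the others, the lowest and highest counts were GRα 244 to 1823, GRα-A 880 to 3863, GRα-B 840 to 2571, GRα-C3 1309 to 3750, GRα-D3 411 to 2501, GRα-A against GRα 0 to 5, GRα-B against GRα 0 to 66, GRα-C3 against GRα 2 to 48, GRα-D3 against GRα 6 to 24, GRα-B against GRα-A 0 to 7, GRα-C3 against GRα-A 0 to 1, GRα-D3 against GRα-A 15 to 188, GRα-C3 against GRα-B 0 to 33, GRα-D3 against GRα-B 0 to 187, GRα-D3 against GRα-C3 79 to 457, the F-test 0 to 211, the vehicle F-test 1 to 3. Models of the 20 arrays treat arrays as units, so their higher counts do not come from more replicates. They estimated negative correlations between the arrays of a replicate (−0.481 with a random replicate, −0.24 with a dye term, −0.549 with the day as a block, −0.097 with a dye term per batch). How much of the rise came from these correlations and how much from the larger number of units was not tested. The stricter thresholds lower counts by construction. The fit of fewer lines estimates another spread from fewer samples.

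Of the named values, 465 were calls in a line. Of these, 223 were kept without each replicate in turn where a value was left, 203 under every other setting chosen beforehand and 156 under all. Of 36 named differences of 2 lines, 3, 2 and 2 were kept in that order, and of 15 F-test genes 0, 1 and 0. Among called values only CD79A in GRα-A changed sign, to −0.026 with median centring. Values below the threshold in both fits changed sign 2 times with median centring, 1 time each with scaling, the replicate block and the omission of the array with conflicting labels, and at most 3 times without any 1 replicate. The median over all probes lay at most 0.036 from 0 in any line under the main and 4 other signal settings. The replicate number, which is also the scanner batch, gave as a block 1521, 3535, 2727, 3535 and 2288 calls in the lines. Of the 83 F-test probes, 76 were shared with the block, 64 with the fit less the array with conflicting labels, 25 with the deposited log ratios, 16 with median centring, 24 with scaling and 10 without background correction. Local background differed between batches, and its effect on dim probes was not tested itself. With no filter on dim probes 552 of 552 named values stayed called or not called as before. With only probes well above background in both channels on all 20 arrays, 540 of 542 did.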

Other observations

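The matching of lines between batches was written before its result was seen, and no tests in this part were chosen afterwards. The genes were picked after their values were seen.

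Some genes were called in opposite directions in 2 lines and also passed the F-test. PMP22, a protein of peripheral myelin, had −0.32 in GRα-A and 0.42 in GRα-D3 (limma adjusted p = 0.0327 over the lines). MFAP2, a microfibril protein, had 0.28 in GRα-B and −0.54 in GRα-D3 (limma adjusted p = 0.0183). CDCA2, a mitotic chromatin regulator, had −0.52 in GRα-C3 and 0.20 in GRα-D3 (limma adjusted p = 0.0206), and KATNA1, which severs microtubules, had −0.30 and 0.24 in the same lines (limma adjusted p = 0.0235). APBB2, an adaptor protein, had 0.36 in GRα-B and −0.31 in GRα-D3 (limma adjusted p = 0.0235).

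A hypothesis was that each line has a response of its own that recurs between the scanner batches. The mean correlation of the deviations of the same line between batches was 0.279 (0.215, 0.312, −0.09, 0.347 and 0.614 in the order of the lines), and 2 of the 120 ways to match lines gave a value as high (exact permutation p = 0.017), with a highest of 0.307. The prediction asked for the highest of all, so the hypothesis stays open. It may hold for GRα-D3 (0.614) and was not borne out for GRα-B (−0.09).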
